A study of Sus scrofa with 6 samples.

How the data were processed

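RNA of mature pig oocytes was measured on 6 Affymetrix porcine arrays, 3 from adult and 3 from prepubertal females. Per the labels' protocols, poly(A) RNA was captured on oligo-dT beads, amplified in 2 cycles, converted to biotinylated cRNA and hybridized, so values come mainly from the 3′ ends of polyadenylated transcripts. Poly(A) capture also makes the signal depend on tail length, which changes for many stored mRNAs while an oocyte matures. The deposited values are MAS5 signal values, 1 per probe set and array, on a linear scale, per the submitters' processing notes, which name MAS5. The MAS5 version and its scaling target are not given in the sources used here. The design fixed before the data were examined assumed values scaled by MAS5 to a common level. The deposited arrays did not share one: their 2% trimmed means lay between 106 and 161. The planned fit on the deposited values was kept, and the results after quantile normalization stand beside it. Every value column matched a sample, with 0 columns left unmatched.

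The table held 24123 probe sets. The 124 Affymetrix control probe sets were left out of the tests, leaving 23999. A constant of 16 was added to each signal before taking log2, which damps noise near background and understates the fold of dim genes, and all folds are on this log2(signal + 16) scale. Probe sets were tested if their mean log2 value over all 6 arrays was at or above the median, which left 12000. Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend), prepubertal minus adult, 2-sided, with Benjamini-Hochberg adjustment over the tested probe sets and a threshold of 0.05. All adjusted p-values of genes are from this limma fit. The number of arrays limits the precision.

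Gene symbols came from the platform's annotation table, which lists 10297 probe sets. Of the non-control probe sets, 10069 had 1 gene symbol, 198 had several and were left unnamed, and 13732 were not listed and are unnamed here. For 9989 of the 10069 the symbol was looked up by Entrez identifier in RefSeq's gene table for the assembly Sscrofa11.1, and the others kept the annotation's symbol. Of the tested probe sets 5761 had 1 symbol, for 4600 genes. No coordinates are given, because the values carry no genome build.

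The genes named in the text followed a rule fixed before the data were examined. It took, among tested probe sets with 1 symbol, 1 per gene, past an adjusted p of 0.05 and without overlap between groups, the 15 with the largest change in each direction. A direction with fewer than 10 was filled to 10 by the smallest unadjusted p among genes without overlap. Added to these were up to 4 members of each list past the threshold, the 2 members of each list with the smallest unadjusted p, the 2 brightest members of each marker list, and GDF9, BMP15, ZP3, ACTB and GAPDH whatever their result.

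The gene lists fixed before the data were examined were oocyte genes; meiotic maturation and cell cycle kinases with cyclins and other regulators; spindle and chromosome segregation; maternal mRNA deadenylation and translation control; translation initiation and elongation factors; cytosolic and mitochondrial ribosomal proteins. Metabolic lists were glycolysis, the pentose phosphate pathway, pyruvate and the tricarboxylic acid cycle, oxidative phosphorylation, fatty acid oxidation, lipid synthesis, storage and cholesterol, and solute and amino acid transporters. The others were glutathione and antioxidant defence, chaperones and endoplasmic reticulum stress, ubiquitin and proteasome, apoptosis, DNA repair, DNA methylation and chromatin modification, histones and histone chaperones, TGF-beta and BMP signalling, gap junction and oocyte-cumulus contact, and calcium release and egg activation. Marker lists covered cumulus and granulosa cells, theca and stroma, blood and immune cells, and endothelium. For list tests the probe set with the highest mean stood for its gene, and lists with at least 5 tested genes were tested with limma's camera at a preset correlation of 0.01, adjusted over all lists. Camera with an estimated correlation and limma's fry were run beside it. With an estimated correlation 0 lists passed (lowest adjusted p 0.984 as deposited and 0.878 after quantile normalization), as with the preset one. Marker levels and 3′ to 5′ ratios were compared with exact permutation tests, 2-sided, whose smallest possible p is 0.1.

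The alternatives planned in advance were other added constants, filters, normalizations and variance models, array weights, the replicate number as a block, other ways to represent genes and test lists, other thresholds, and leaving out each array. Scaling to a common trimmed mean, scaling to the hybridization controls, and combinations with quantile normalization were chosen after seeing the data. The fit was tested on simulated data with 12000 probe sets and the spread of these arrays, with 200 changed, in 20 simulations. At 3 against 3 arrays it recovered 2% of log2 changes of 0.5, 26.9% of 1, 68.4% of 1.5 and 86.8% of 2, and 3.66% of its calls were false. Camera, tested on simulated data with 4600 genes, found 100% of lists of 20 genes shifted by 0.5 and 5% of unshifted lists at an unadjusted p of 0.05. The simulated probe sets and genes varied independently, so these rates need not hold for real lists whose genes move together. The simulations also held no shift of whole arrays and no array unlike its group. Their share of false calls therefore need not hold for the calls on the real arrays. Figures were drawn with matplotlib 3.10.9.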

Results

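Gene expression was measured on Affymetrix porcine arrays in mature oocytes, the egg cells, of adult and prepubertal female pigs. The labels describe the adult oocytes as developmentally competent and the prepubertal ones as incompetent, so the comparison asks which mRNAs differ between eggs of high and low capacity to develop. Each group had 3 arrays, named in the labels as biological replicates. Oocytes came from ovarian follicles of 2 to 6 mm and were matured in culture for 42 to 44 h. The surrounding cumulus cells were then stripped off with hyaluronidase and vortexing, and the first polar body was checked, so the oocytes had reached metaphase II, the stage at which an egg awaits fertilization. The labels do not say how many oocytes or animals stood behind an array, so the p-values measure the spread between these samples.

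The arrays were not at a common level as deposited. The 2% trimmed mean signal was 161, 123 and 142 in adult replicates 1, 2 and 3 and 132, 106 and 115 in prepubertal replicates 1, 2 and 3. The group means were 142 ± 19.4 and 118 ± 13.1 (SD, n = 3), a log2 difference of −0.27 (exact permutation p = 0.2, 2-sided). With 3 arrays against 3 this test cannot give a p below 0.1. The bacterial hybridization controls, RNAs spiked into the hybridization mix, differed by 0.15 on the log2 scale in the other direction (exact permutation p = 0.3). On log2 values, pairs of adult arrays correlated at 0.976 to 0.980 across probe sets, pairs of prepubertal arrays at 0.968 to 0.976, and pairs across the groups at 0.965 to 0.976, with genes not being independent replicates.

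**Figure D1:**
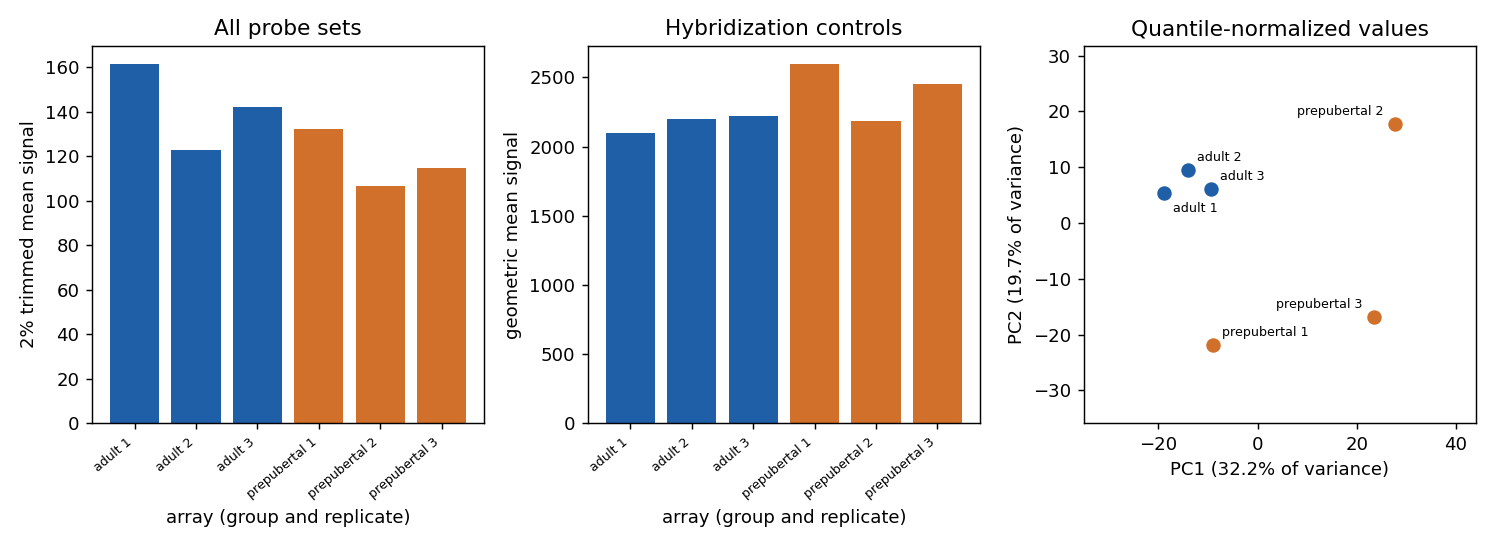
Level and grouping of the 6 arrays (blue, adult; orange, prepubertal): 2% trimmed mean signal over all probe sets, geometric mean signal of the hybridization controls, and the first 2 principal components of the quantile-normalized log2 values, which carried 32.2% and 19.7% of the variance. Prepubertal replicate 1 lay at −8.94 on the first component, beside adult replicate 3 at −9.35, while prepubertal replicates 2 and 3 lay at 27.7 and 23.4.

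In prepubertal oocytes 1 probe set each of 15 genes named by the fixed rule was lower and of 4 genes higher. The largest drop among named genes was in ERP29, which encodes a folding factor of the endoplasmic reticulum. Its signal was 118 ± 10.6 in prepubertal and 423 ± 47.9 in adult oocytes (SD, n = 3 arrays each), 3.26-fold lower, with a log2 difference of −1.70 ± 0.22 (SE) and a limma adjusted p of 0.000817. TPM4, a tropomyosin that binds along actin filaments, was 3.04-fold lower, at 96.3 ± 24.0 against 332 ± 116 (adjusted p = 0.00866). Chromatin proteins were among the others: SMARCE1, a subunit of the SWI/SNF remodelling complex, was 2.88-fold lower (log2 difference −1.53 ± 0.24, adjusted p = 0.00526). SMARCA5, the ATPase of ISWI remodelling complexes, was 2.61-fold lower (−1.38 ± 0.29, adjusted p = 0.0308), and CFDP1, another chromatin-associated protein, was 2.56-fold lower (−1.36 ± 0.23, adjusted p = 0.00866).

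CLSPN, which encodes claspin, the adaptor that lets the kinase ATR activate checkpoint kinase 1, was 2.72-fold lower (log2 difference −1.44 ± 0.27, adjusted p = 0.0174). CHEK1, which encodes checkpoint kinase 1 itself, was 2.26-fold lower (−1.18 ± 0.23, adjusted p = 0.0235), and REV1, a DNA polymerase that copies past damaged bases, was 2.16-fold lower (adjusted p = 0.0371). The dynein light chain gene DYNLT1 dropped from a high level, 4918 ± 779 in adult to 1932 ± 853 in prepubertal oocytes, 2.66-fold lower (adjusted p = 0.00526). CEP57, a centrosome protein, was 2.23-fold lower (adjusted p = 0.0263). The remaining named genes were PLAC8 (2.31-fold lower), TOMM34 (2.22-fold), NSA2, a factor of ribosome assembly (2.17-fold), MAPK6, an atypical MAP kinase (2.15-fold), and MRPL3, a protein of the mitochondrial ribosome (2.10-fold), with adjusted p between 0.0263 and 0.0495.

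The genes that rose included a pair of SR proteins, splicing factors with arginine-serine repeats. SRSF4 was 2.96-fold higher in prepubertal oocytes, at 458 ± 90.8 against 149 ± 62.6 (SD, n = 3 arrays each; log2 difference 1.56 ± 0.26 SE, limma adjusted p = 0.00866), and SRSF7 was 2.04-fold higher, at a mean of 315 against 148 (1.03 ± 0.23, adjusted p = 0.0441). TPM1, another tropomyosin, was 2.94-fold higher (adjusted p = 0.0263). PRKACA, which encodes a catalytic subunit of the cAMP-dependent protein kinase, the enzyme that holds oocytes in meiotic arrest before they mature, was 2.78-fold higher (adjusted p = 0.0441). In adult oocytes both lay near background, with mean signals of 19.2 for TPM1 and 34.2 for PRKACA, so their folds depend on the constant added before taking logs. The 6 genes that filled this direction did not pass the threshold: NCAPD3, a condensin subunit, had a log2 difference of 0.94 ± 0.23 (adjusted p = 0.0713), GTF2I 1.15 ± 0.29 and RDH11 1.11 ± 0.29, followed by PARP3 at 0.90, GPATCH3 at 0.98 and CACNB3 at 0.94, with adjusted p up to 0.188. GTF2I, PARP3, GPATCH3 and CACNB3 also lay near background in adult oocytes, with mean signals of 9.44, 19.1, 9.86 and 7.34. Their differences too depend on the added constant. A further GTF2I probe set had lower values as deposited and higher ones after quantile normalization.

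**Figure D2:**
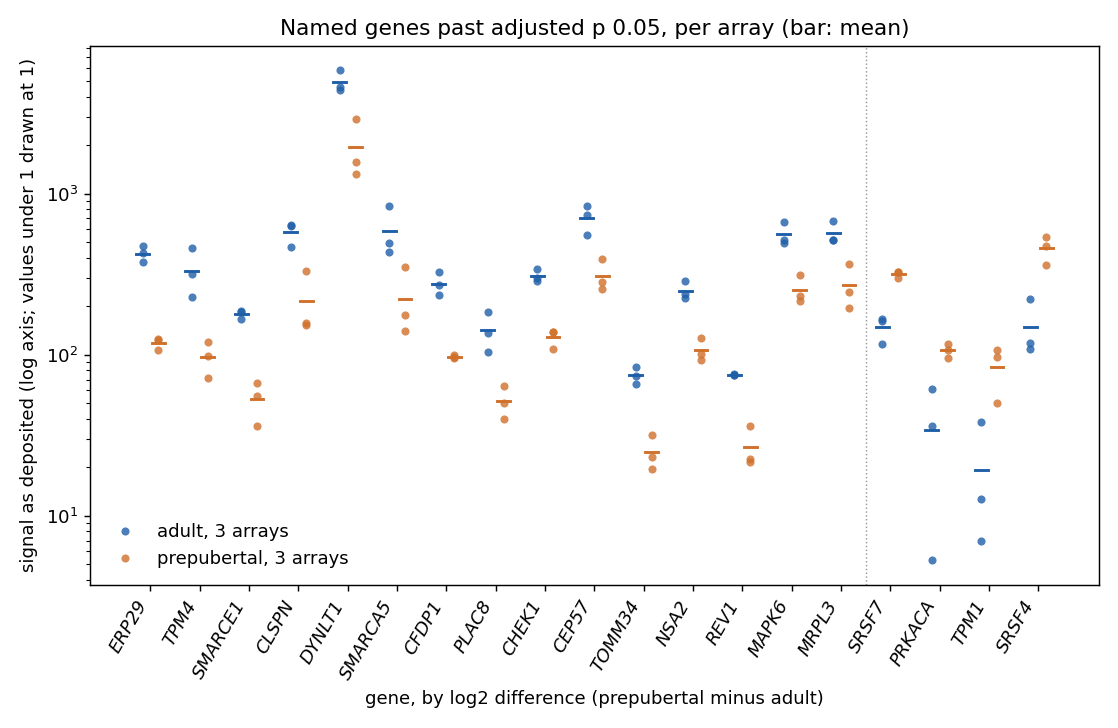
Deposited signal (log axis) of each array for the 19 genes of the first part of the naming rule, in the order of their log2 difference; dots are single arrays and bars are means, blue for adult and orange for prepubertal. The groups did not overlap in any of these genes, and the dotted line divides the 15 lower genes, led by ERP29, from the higher SRSF7, PRKACA, TPM1 and SRSF4.

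Some of these genes were measured by further probe sets, which did not all move alike. A brighter TPM1 probe set had the same level in both groups (log2 difference 0.01), and a brighter CHEK1 probe set was 1.24-fold lower without passing the threshold (adjusted p = 0.461). The other MRPL3 probe sets had values 1.18-fold and 1.10-fold higher (adjusted p = 0.734 and 0.762), and the brightest of them, at 1.32-fold higher after quantile normalization, passed there adjusted over the list alone (0.043), so MRPL3 has no single direction. The 2 other SMARCA5 probe sets had values 1.39-fold and 1.27-fold lower (adjusted p = 0.322 and 0.50), and the second CLSPN and CFDP1 probe sets 1.46-fold and 1.32-fold lower (adjusted p = 0.421 and 0.547). After quantile normalization these further probe sets differed less: 1.02-fold lower for CHEK1, 1.01-fold for MAPK6, 1.15-fold and 1.06-fold for SMARCA5, 1.23-fold for both CLSPN and CFDP1, 1.64-fold for REV1 and 1.53-fold for TPM4, while TPM1's was 1.18-fold higher. A brighter MAPK6 probe set was 1.24-fold lower (adjusted p = 0.398) and a brighter REV1 probe set was 1.98-fold lower (adjusted p = 0.0637). The second TPM4 probe set was 1.71-fold lower (adjusted p = 0.198).

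Of 12000 probe sets tested with limma, 57 passed an adjusted p of 0.05, 4 higher and 53 lower in prepubertal oocytes. At an unadjusted p under 0.05 there were 137 higher and 1632 lower, where chance gives 600 in all. All 57 separated the groups without overlap, as did 18.95% of the tested probe sets, where chance gives 10%. Only 25 of the 57 carried a single gene symbol. Of these, EIF4G2, a translation initiation factor, was 1.68-fold lower and PGD, a dehydrogenase of the pentose phosphate pathway, 2.05-fold lower. DLG5 (1.69-fold lower), GALNT11 (1.80-fold), ARID4A (1.91-fold) and ANAPC4, a subunit of the anaphase-promoting complex (1.91-fold), fell outside the naming rule and were chosen after their values were seen. Of their further probe sets, 3 of ARID4A had values 1.34-fold, 1.12-fold and 1.10-fold lower (after quantile normalization 1.19-fold lower and 1.00-fold and 1.10-fold higher), 1 of DLG5 1.03-fold higher and 1 of GALNT11 1.33-fold lower. Single arrays decided how many probe sets passed. Without adult replicate 1, 2 or 3 the count was 6, 3 or 16, of which 6, 2 and 15 were among the 57. Without prepubertal replicate 2 or 3 it was 20 or 35, of which 17 and 27 were among the 57. Without prepubertal replicate 1 it was 658 (60 higher, 598 lower), with all 57 among them. ERP29 passed in each of these 6 fits (adjusted p at most 0.0171).

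The median log2 difference of all tested probe sets was −0.20 as deposited and −0.01 after quantile normalization, which brings the arrays to one distribution. After quantile normalization 14 probe sets passed, 3 higher and 11 lower (78.6% lower against 93.0% as deposited), and 13 of these were among the 57. Scaling to a common trimmed mean, added after seeing the data, gave 4 higher and 16 lower (80% lower). At an unadjusted p under 0.05, quantile normalization gave 607 higher and 695 lower and trimmed-mean scaling 687 higher and 632 lower. Median centring gave 234 higher and 1103 lower and scaling to the hybridization controls 74 higher and 3152 lower, with medians of −0.11 and −0.32 left among the tested probe sets. The genes past the threshold after quantile normalization were ERP29 (2.73-fold lower), TPM4 (2.58-fold), SMARCE1 (2.50-fold), DYNLT1 (2.21-fold), CFDP1 (2.18-fold), CEP57 (1.85-fold), SRSF4 (3.52-fold higher) and SRSF7 (2.43-fold higher). One more passed only there, a probe set of the histone chaperone SET (log2 difference 0.82, adjusted p = 0.0375, against 0.54 and 0.189 as deposited). The other named genes that passed as deposited kept their direction, with adjusted p from 0.0528 to 0.127. After quantile normalization the count was 2, 0 or 4 without adult replicate 1, 2 or 3 (931 at an unadjusted p under 0.05 in limma without adult replicate 2). It was 199 (108 higher, 91 lower), 6 or 3 without prepubertal replicate 1, 2 or 3.

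The fixed gene lists were compared next, to see whether whole pathways differed between the eggs. None of the 27 lists with at least 5 tested genes passed limma's camera test, which sets a list against all other genes (lowest adjusted p 0.495 as deposited and 0.413 after quantile normalization). At an unadjusted p under 0.05 there was 1 list as deposited and 2 after quantile normalization. The fry test of a shift in one direction called 0 lists in either setting (lowest adjusted p 0.275 and 0.121). Its test of change in either direction called 0 as deposited and 12 after quantile normalization. All 27 medians lay below 0 as deposited and 17 lay above 0 after quantile normalization. As deposited, camera placed 13 of these lists, glycolysis among them, above the other genes despite medians below 0. After quantile normalization the median, mean and test differed in sign for the meiotic maturation, spindle, cytosolic ribosomal, tricarboxylic acid cycle, fatty acid oxidation, antioxidant, DNA repair, chromatin modification, transporter, calcium and cumulus lists. Adjusted over the list alone, 14 members of 10 lists passed as deposited, all 14 with lower values, against 2 over all probe sets. ACVR1 is counted among the 14 both as an oocyte gene and in the TGF-beta and BMP list. After quantile normalization 11 members passed, 7 with higher values (SET, CNOT7, MRPL39, MRPL3, MRPL43, UQCRB and SLC1A5) and 4 with lower ones (ATP2B1, MRPL11, PGD and EIF4G2), and only these last 4 were among the 14.

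**Figure D3:**
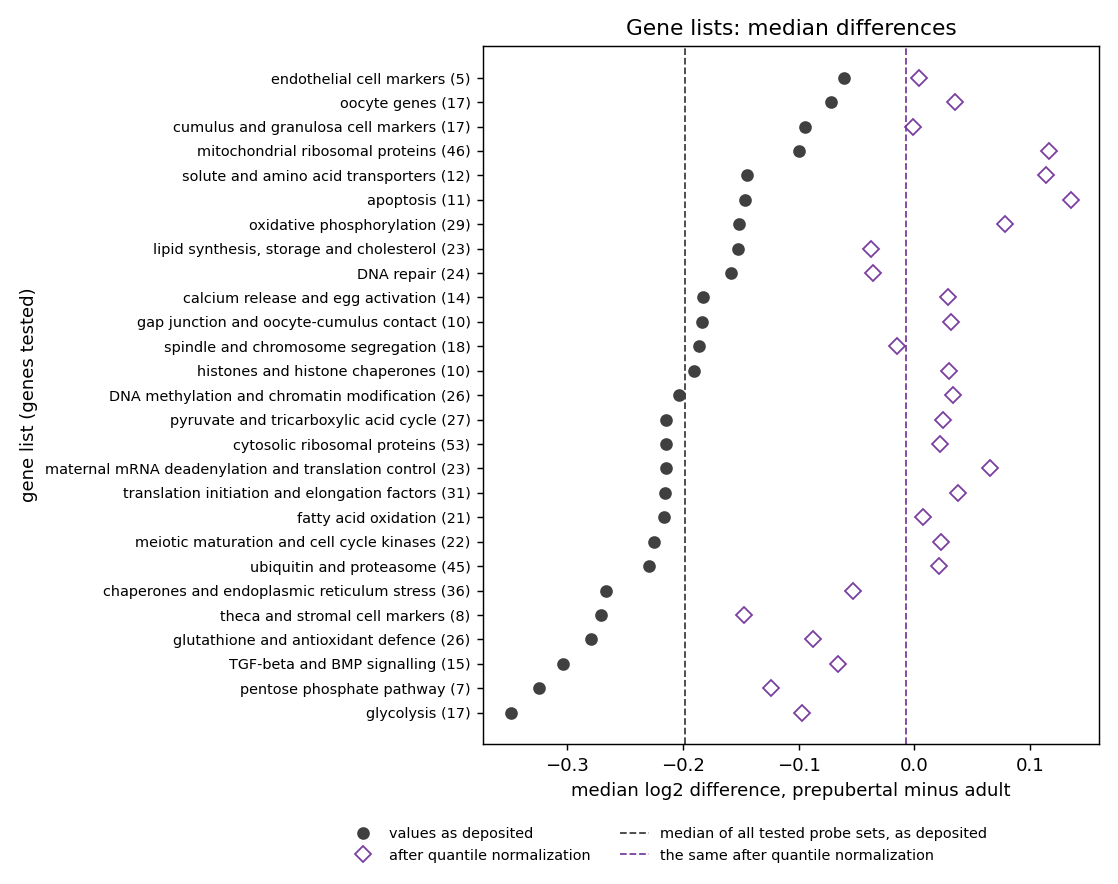
Median log2 difference (prepubertal minus adult) of each fixed list's tested genes, with the number of genes in brackets; filled circles are values as deposited, open diamonds values after quantile normalization, and dashed lines the medians of all tested probe sets. The deposited medians scattered around −0.20 and the normalized ones around −0.01, with no list past the camera threshold.

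Genes typical of the oocyte were measured in both groups. Of 17 tested oocyte genes 13 had lower values as deposited and 6 after quantile normalization, with a median log2 difference of −0.07 as deposited and 0.04 after quantile normalization. The secreted growth factors of the oocyte had signals of 231 ± 66.6 in prepubertal and 360 ± 137 in adult oocytes for GDF9 (adjusted p = 0.327) and 195 ± 35.9 and 169 ± 27.7 for BMP15 (adjusted p = 0.74). The egg coat gene ZP3 had 429 ± 42.9 and 543 ± 122 (adjusted p = 0.53), and the reference genes ACTB and GAPDH had log2 differences of −0.23 and 0.07 as deposited and 0.05 and 0.34 after quantile normalization. The BMP receptor gene ACVR1 had values 1.70-fold lower, past the threshold adjusted over the list alone as deposited (0.0245), but not after quantile normalization (0.060) or over all probe sets (0.106). A dimmer ACVR1 probe set had values 1.06-fold higher, and POU5F1 had values 1.53-fold lower (adjusted p = 0.246). In the TGF-beta and BMP list (15 tested, median −0.30 and −0.07 after quantile normalization), ID3 followed, with values 1.35-fold lower. Quantile normalization left ACVR1, POU5F1 and ID3 at values 1.41-fold, 1.29-fold and 1.15-fold lower. In the list of meiotic maturation and cell cycle kinases, cyclins and other regulators (22 tested, median −0.23, 0.02 after quantile normalization), PKMYT1, which inhibits CDK1, had values 1.74-fold and AURKA 1.44-fold lower (adjusted p = 0.193 and 0.278). Spindle and segregation genes (18 tested, median −0.19, −0.02 after quantile normalization) held the cohesin gene RAD21, with values 1.67-fold lower, and TUBA1B, at 1.25-fold. Quantile normalization left PKMYT1 and AURKA at values 1.59-fold and 1.18-fold lower, and RAD21 and TUBA1B at 1.37-fold and 1.03-fold. Of 14 genes of calcium release and egg activation (median −0.18, 0.03), the calcium pump gene ATP2B1 had values 1.88-fold lower (adjusted p = 0.0532 over all probe sets, 0.00366 over the list alone) and CAMK2G 1.83-fold. In the gap junction and cumulus contact list (10 tested, median −0.18, 0.03), FYN had values 1.40-fold and MSN 1.34-fold lower. A further FYN probe set had higher values.

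In the lists of protein synthesis, EIF4G2 fell from 11859 ± 1581 to 7143 ± 1645 and was the 1 member of the 31 translation factors past the threshold (adjusted p = 0.0291), with EIF2B2 next at 1.76-fold lower values (adjusted p = 0.251; list median −0.22, 0.04 after quantile normalization). The 53 cytosolic ribosomal proteins had a median of −0.21 (0.02), and RPL6, with values 1.90-fold lower, and RPS27, at 2.15-fold, passed adjusted over the list alone as deposited (both 0.028), but not after quantile normalization (0.132 and 0.206) or over all probe sets (0.0857 and 0.0982). The 46 mitochondrial ribosomal proteins lay above the other genes at an unadjusted camera p of 0.0392 (0.0306 after quantile normalization; 0.399 and 0.151 with an estimated correlation), with a median of −0.10 (0.12). MRPL11 and MRPL16 of this list had values 1.88-fold and 1.46-fold lower (adjusted p = 0.0713 and 0.208). In the list of maternal mRNA deadenylation and translation control (23 tested, median −0.21, 0.07), PAN2 and PABPC4 had values 1.44-fold and 1.35-fold lower (adjusted p = 0.278 and 0.288). Quantile normalization left PAN2 and PABPC4 at values 1.18-fold and 1.11-fold lower, and MRPL11 and MRPL16 at 1.56-fold and 1.20-fold. EIF4G2 and EIF2B2 were then at 1.62-fold and 1.68-fold lower values, and RPL6 and RPS27 at 1.58-fold and 1.92-fold.

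Among metabolic lists, PGD was the 1 called member, in a pentose phosphate list whose 7 tested genes all had lower values as deposited and 5 of 7 after quantile normalization (median −0.32 and −0.12). PRPS1 of this list had values 1.33-fold lower. Glycolysis had the lowest median as deposited, −0.35 over 17 genes, but not after quantile normalization (−0.10), although camera placed it slightly upward as deposited (adjusted p = 0.965). The hexokinase gene HK1 had values 1.93-fold lower (adjusted p = 0.0352 over the list alone, 0.0955 after quantile normalization, 0.128 over all probe sets) and the glucose transporter gene SLC2A3 1.87-fold. The pyruvate and tricarboxylic acid cycle list (27 tested, median −0.21, 0.02) held PDK3, with values 1.63-fold lower, and SDHA, at 1.48-fold. Oxidative phosphorylation (29 tested, median −0.15, 0.08) held NDUFA3 and NDUFA1, with values 1.70-fold and 1.33-fold lower. No fatty acid oxidation gene reached an unadjusted p of 0.05 (21 tested, median −0.22, 0.01), with HADH at 1.30-fold and DECR2 at 1.46-fold lower values. In lipid synthesis (23 tested, median −0.15, −0.04), ELOVL6 and the cholesterol enzyme gene MSMO1 had log2 differences of −0.58 and −0.74 and passed adjusted over the list alone as deposited (adjusted p = 0.0419 and 0.0488), but not after quantile normalization (both 0.106). Dimmer probe sets had values 1.30-fold and 1.00-fold higher for ELOVL6 and 1.12-fold higher for MSMO1. Of 12 transporters (median −0.14, 0.11), SLC25A4 had values 1.46-fold lower.

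Antioxidant genes (26 tested, median −0.28, −0.09 after quantile normalization) held TXN, which encodes thioredoxin, with values 1.57-fold lower (adjusted p = 0.0272 over the list alone, 0.0950 after quantile normalization, 0.0982 over all probe sets), and GSTO1, at 1.61-fold. Chaperone genes (36 tested, 32 with lower values as deposited and 20 after quantile normalization, median −0.27, −0.05) held HSP90AA1 and CCT7, with values 1.38-fold and 1.58-fold lower. The proteasome list (45 tested, median −0.23, 0.02) held PSMA7 and CUL1, at 1.45-fold and 1.34-fold. Apoptosis genes (11 tested, median −0.15) lay above the other genes after quantile normalization at an unadjusted camera p of 0.0231 (median 0.13; 0.0757 with an estimated correlation); PDCD10 and AIFM1 had values 1.40-fold and 1.24-fold lower as deposited. In the DNA repair list (24 tested, median −0.16, −0.04), represented by the brightest probe set per gene, ERCC1 had values 1.75-fold and RPA1 1.34-fold lower. Chromatin modifiers (26 tested, median −0.20, 0.03) held HDAC6 and HDAC3, with values 1.79-fold and 1.62-fold lower, although the 1 further HDAC6 probe set and 1 of 2 further HDAC3 probe sets had higher values. The histone list (10 tested, median −0.19, 0.03) held NAP1L4, at 1.44-fold lower, and SET, whose brightest probe set was 1.23-fold higher (adjusted p = 0.305). Quantile normalization left TXN at values 1.30-fold lower, GSTO1 at 1.39-fold, HSP90AA1 at 1.15-fold and CCT7 at 1.30-fold. PSMA7 was then at 1.19-fold lower values, CUL1 at 1.11-fold, PDCD10 at 1.15-fold and AIFM1 at 1.08-fold. ERCC1 was at 1.65-fold lower values, RPA1 at 1.10-fold, HDAC6 at 1.65-fold, HDAC3 at 1.37-fold and NAP1L4 at 1.20-fold. This SET probe set was 1.39-fold higher.

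Markers of other ovarian cells were measured to see whether remnants of these differed between the samples. Over all measured markers without a filter, the mean log2 level per array differed by −0.11 for cumulus and granulosa cells (31 genes, exact permutation p = 0.2), −0.19 for theca and stroma (18 genes, exact p = 0.1), −0.16 for blood and immune cells (21 genes, exact p = 0.1) and 0.02 for endothelium (11 genes, exact p = 0.6). None passed after adjustment over the exact tests run (lowest 0.333), and none could, as the smallest possible exact p is 0.1. The theca and blood lists reached that smallest p, so this does not show that remnants were alike. After quantile normalization the difference was −0.12 for theca and stroma (exact p = 0.1) and −0.10 for blood and immune cells (exact p = 0.2). For cumulus and granulosa cells it was −0.02 (exact p = 0.6) and for endothelium 0.11 (exact p = 0.2). Most of these markers were dim: ITIH2 and FST of the cumulus list had signals of 27.0 ± 6.05 and 128 ± 24.1 in adult oocytes and 10.7 ± 6.50 and 92.0 ± 1.81 in prepubertal ones, while its brightest genes, LAMB1 and INHBA, had values 1.21-fold and 1.22-fold lower. In the theca list COL3A1 and ENG had values 1.81-fold and 1.79-fold lower (adjusted p = 0.214 and 0.243), PDGFRB 1.19-fold lower and COL1A2 1.03-fold higher. HBB, the beta-globin gene, had values 1.44-fold and SLA-DQA1 1.26-fold lower, and ALAS2 1.10-fold higher. In the endothelial list EGFL7 and ESAM had values 1.28-fold and 1.16-fold higher and PECAM1 1.09-fold lower. Quantile normalization left LAMB1 and INHBA at values 1.00-fold and 1.05-fold lower, COL3A1 and ENG at 1.68-fold and 1.70-fold and HBB at 1.21-fold. EGFL7 was then at 1.46-fold higher values. In the list tests, the tested cumulus (17), theca (8) and endothelial (5) markers had medians of −0.09, −0.27 and −0.06 (0.00, −0.15 and 0.00 after quantile normalization), the endothelial mean being 0.05, and the blood list had 4 tested genes, too few for the list test.

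The ratio of 3′ to 5′ control probe sets, a measure of how far amplification reached along an mRNA, had log2 means of 7.98 ± 0.32 in adult and 7.79 ± 0.40 in prepubertal arrays for actin (SD, n = 3; exact permutation p = 0.7). For elongation factor 1-alpha these were 5.30 ± 0.50 and 5.19 ± 0.36 (exact p = 0.9, n = 3), and for GAPDH 3.30 ± 0.29 and 2.80 ± 0.31 (exact p = 0.2, n = 3). The 5′ actin probe set lay near 0 signal in both groups, at 4.34 ± 4.13 and 5.84 ± 7.68, and the 5′ GAPDH probe set below the added constant of 16, at 3.96 ± 2.75 and 10.8 ± 5.55, so both ratios are set largely by that constant.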

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

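The tests of dimmer scanning, of whole-array shifts, of a swap and of shared handling were chosen only after their results were seen. The 18 families of control probe sets were left out of the main comparison of genes. Among them the bioD control, part of the hybridization control mean given above, was 0.18 higher in prepubertal arrays on the log2 scale. Every prepubertal array lay above every adult one (exact permutation p = 0.1, the smallest possible, adjusted p = 0.3 over the control families). The erythropoietin receptor and IRP controls, near background, also had every prepubertal array above (0.19 and 0.20). Other families went the other way: 5S rRNA (−0.69), lys (−0.18) and trp (−0.13), all 3 near background, had every prepubertal array below every adult one at the same exact p of 0.1 (adjusted p = 0.3), and 28S rRNA differed by −0.66 (exact p = 0.2).

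As deposited, 53 of the 57 probe sets past the threshold were lower in prepubertal oocytes. Dimmer staining or scanning of the prepubertal arrays would lower the hybridization controls as well, but these were 0.15 higher while the trimmed mean differed by −0.27 (log2 difference of the ratio −0.41, exact permutation p = 0.1), which argues against it. The median size of these 57 was 1.15 (median SE 0.23) as deposited and 0.96 (0.19) after quantile normalization. The median removed was 0.25, and all 57 kept their sign. They were selected for large differences, so this cannot decide whether a shift of whole arrays alone lifted them past the threshold. After quantile normalization only 13 stayed past it and 43 were under a limma adjusted p of 0.10. At an unadjusted p under 0.05 there were 1302 probe sets against 1769 as deposited, and the cause was not tested. For the wider excess of lower values at an unadjusted p under 0.05 the share went from 92.3% to 47.9% after trimmed-mean scaling, which sets this outcome itself, and to 82.5% after median centring, which left a median of −0.11 among the tested probe sets, so a technical shift and less mRNA per prepubertal oocyte cannot be told apart. Of the 10 splits of the 6 arrays only the real one, 1 of 10, gave as many probe sets (57, highest other 7, and 14 after quantile normalization, highest other 4), and 10 splits are too few for a share under 0.05.

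Prepubertal replicate 1 lay nearer the adult arrays than its own group, with a mean correlation to its own group minus that to the adult group of −0.00658 after quantile normalization. A swap with an adult array is argued against, because each adult array correlated better with its own group, by at least 0.00614. A single wrong label remains open: on 200 probe sets chosen without it, it lay at 0.275 of the way from the adult to the prepubertal mean, against 0.65 to 0.787 for the other 5 arrays in their own direction, between the bounds of 0.25 and 0.5 set for a wrong and a right label. Shared handling of the replicate 1 arrays also remains open, as their deviations correlated at 0.0821, under the bound of 0.1 and above 0. A less complete difference in that batch of prepubertal oocytes is a biological possibility that was not tested.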

How the results depend on the processing

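Scaling to the trimmed mean or the hybridization controls, and each combination with quantile normalization, were chosen after seeing the data; the other settings were planned. All 57 probe sets past the threshold kept their sign in every setting that tested them (48 of them at the 75th percentile filter), but the count moved widely, from 57 (4 higher, 53 lower) to the following. It was 15 (1 higher, 14 lower) with a constant of 1, 1 (0 higher, 1 lower) without a filter on low values, 173 (7 higher, 166 lower) with a filter at the 75th percentile, 14 (3 higher, 11 lower) after quantile normalization, and 7 (1 higher, 6 lower) after median centring. It was 1 (0 higher, 1 lower) without an intensity trend, 1259 (110 higher, 1149 lower) with array weights, 20 (4 higher, 16 lower) with arrays scaled to a common trimmed mean, 604 (9 higher, 595 lower) with arrays scaled to the hybridization controls, and 132 (8 higher, 124 lower) at an adjusted p under 0.10. It stayed within 1.5 times with a constant of 64 (65), a filter at the 25th percentile (68) and a robust variance (50). Leaving out 1 array gave from 3 (0 higher, 3 lower) to 658 (60 higher, 598 lower), and from 0 (0 higher, 0 lower; 931 at an unadjusted p under 0.05) to 199 (108 higher, 91 lower) after quantile normalization. Fewer arrays can lower the counts, but the count rose without prepubertal replicate 1. The cause of these moves was not tested.

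With the replicate number as a block the count was 918 (29 higher, 889 lower) as deposited and 32 (10 higher, 22 lower) after quantile normalization. The labels give no reason for pairing, and same-numbered arrays deviated together at correlations of 0.11, 0.06 and 0.03 (0.08, 0.02 and 0.03 after quantile normalization). As deposited every array correlated best with its own number, but after quantile normalization adult replicate 3 and prepubertal replicate 2 did not, and whether the numbers mark shared handling was not settled.

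No list passed in any of the 32 alternatives that test for a shift in one direction; fry's test of change in either direction called 12 lists after quantile normalization. Over the alternatives, the named genes gave 1904 results on the same side of the threshold, 131 newly past it and 276 no longer past it. None turned a direction that had passed. Some genes not past the threshold did turn, such as ACTB, which kept its direction in 19 of 26 alternatives. The marker difference for cumulus and granulosa cells was −0.0186 after quantile normalization, −0.20 with a constant of 1 and −0.0632 with 64. For theca and stroma it was −0.12 after quantile normalization, −0.42 with a constant of 1, −0.0781 with 64 and −0.29 over members above the median, for blood and immune cells −0.10, −0.36, −0.0695 and −0.24, and for endothelium 0.11 after quantile normalization. The GAPDH 3′ to 5′ difference was −1.38 with a constant of 1 and −0.20 with 64, against −0.49. Low signal limits the dim genes: at signals near the constant of 16, as for TPM1 in adult oocytes, a fold is set largely by that constant.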

Other observations

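The tests of the SR-protein family's scaling, of its members without SRSF4 and SRSF7, with an estimated correlation and against the spread of the wider splicing lists, and the 7 lists described here, were chosen only after SRSF4, SRSF7 and the other named genes had been seen past the threshold; the chromatin remodelling, replication checkpoint and tropomyosin lists were built around such genes. Of 11 tested SR-protein genes 7 had higher values in prepubertal oocytes as deposited (median log2 difference 0.18) and 9 after quantile normalization (0.37), where SRSF3 and SRSF11 turned from lower to higher values. Beside SRSF4 and SRSF7, SRSF1 had values 1.66-fold higher (adjusted p = 0.257) and SRSF9 1.20-fold, while SRSF5 and SRSF2 had values 1.55-fold and 1.34-fold lower (adjusted p = 0.264 and 0.398). Dimmer probe sets had values 1.18-fold lower for SRSF9, 1.11-fold and 1.10-fold for SRSF6 and 1.09-fold and 1.05-fold for SRSF10, and 1.22-fold higher for SRSF1. After quantile normalization these were 1.03-fold higher for SRSF9, 1.01-fold lower and 1.01-fold higher for SRSF6. They were 1.04-fold and 1.11-fold higher for SRSF10 and 1.40-fold for SRSF1. The higher value of SRSF11 after quantile normalization was only 1.03-fold. Its dimmer probe sets had values 1.28-fold and 1.16-fold lower as deposited, and stayed lower after quantile normalization, at 1.09-fold and 1.03-fold. Among 51 families of genes sharing a symbol stem, this was the 1 family past limma's camera threshold (adjusted p = 0.000194 as deposited and 0.000722 after quantile normalization). This call rests on the preset correlation of 0.01: with an estimated one 0 of the 51 families passed in limma's camera, and only this 1 had an unadjusted p under 0.05 (0.0321 as deposited and 0.0104 after quantile normalization; adjusted p = 0.992 and 0.528). Among the 7 added lists, SR-related proteins and kinases (14 tested, limma camera adjusted p = 0.645), hnRNP proteins (20 tested, adjusted p = 0.786) and the spliceosome core (34 tested, adjusted p = 0.518) did not pass.

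A hypothesis is that SR-protein mRNAs as a family may be kept at a higher level in prepubertal oocytes. With the preset correlation, a single array is argued against as the source of the call, since the family's camera adjusted p was at most 0.00537 with 1 array left out. It was at most 0.00143 over the scalings and constants tried. Camera sets the family against the other genes, and rescaling whole arrays moves both alike, so the scalings could hardly remove the call and do not test it. All of these fits kept SRSF4 and SRSF7, whose results had drawn attention to the family. For a change of splicing genes as a whole, neither wider list had a camera p under 0.05, the bound set beforehand (lowest 0.133). The median of the hnRNP genes lay below the family's by 0.42 as deposited (SD of the hnRNP genes 0.25) and 0.36 after quantile normalization (SD 0.24). The family's own SD was wider, at 0.64 and 0.67, so such a change remains open. At an unadjusted limma p under 0.05, 3 hnRNP and 4 spliceosome core genes were higher and 0 lower after quantile normalization. As deposited 0 and 1 were higher, and 2 of each list lower. Whether SRSF4 and SRSF7 alone carry it remains open: without them p was 0.0245 as deposited and 0.0131 after quantile normalization, but 0.174 and 0.0614 with an estimated correlation, which the bound first set left out; whether the spliceosome core alone moved with the family is open too, as its median lay 0.35 below after quantile normalization with an SD of 0.37. The real split gave the smallest family p, 1 of the 10 splits (3.80e-06, lowest other 0.0427), and 10 splits are too few for a share under 0.05. The splits also kept SRSF4 and SRSF7, which had drawn attention by their difference under the real split. That split was therefore favoured from the outset, and the comparison cannot decide the question.

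Subunits of chromatin remodelling complexes had lower values in 30 of 30 tested genes as deposited and 20 of 30 after quantile normalization (camera p = 0.000724 and 0.00116; 0.348 and 0.133 with an estimated correlation). Without the 4 genes with a probe set past the threshold, SMARCE1, SMARCA5, CFDP1 and ARID4A, p was 0.0789 and 0.0949. Replication checkpoint genes, with CLSPN and CHEK1, had lower values in 12 of 12 and 7 of 12 (camera p = 0.00335 and 0.0227; 0.256 and 0.134 with an estimated correlation), and p was 0.163 and 0.429 without CLSPN, CHEK1 and REV1. Tropomyosins and tropomodulins had a p of 0.0957 over 5 genes.

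The TPM1 and TPM4 probe sets past the threshold moved in opposite directions, although TPM1's lay near background in adult oocytes and its brighter probe set did not differ. The largest change of all tested probe sets with an adjusted p under 0.05 lay in a probe set unnamed here, with a log2 difference of −2.25 ± 0.28 (adjusted p = 0.000817) and −1.98 after quantile normalization.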
